A study of Drosophila melanogaster with 4 samples.

How the data were processed

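H3K27me2, the dimethylated form of lysine 27 of histone H3, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 h. The series holds 4 samples, namely 2 ChIP samples made with the antibody Ab24684 and 2 input samples. Per the labels' protocols, embryos were crosslinked with 1.8% formaldehyde, and chromatin was incubated with antibody for 15 h. Bowtie 0.12.7 is named in the submitters' processing notes. The region caller, its threshold and the mapping settings are not given in the sources used here.

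The deposited files are 3 lists of significantly enriched regions, 1 for each ChIP sample and 1 for the replicate set as a whole, called the combined list here. Per the file headers, coordinates are those of FlyBase release 5, and positions are given here as in the files, counted from 1. Each region carries the authors' score, a deposited value whose scale the headers do not name. Score values were therefore set against each other only within 1 list, and lists were compared only through ranks, percentiles and shares. Whether the top scores of a list lie at log ratios of whole numbers was tested within each list. How the replicates were pooled into the combined list is not given in the sources used here, so its values are the authors' own and carry no replicate error. Per the labels, the input named replicate 1 served for ChIP replicate 2, and the input named replicate 2 served for ChIP replicate 1, so equal numbers do not mark a matched ChIP and input. The inputs entered no comparison, since no list of their own was analysed here. The headers of both replicate files are written a second time over a truncated first copy, and all region lines below them were read.

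The depth of the libraries is unknown, because the lists hold positions and scores but no read counts. No limit of detection can be given, and a stretch without a region is called uncalled, not unmarked. Labels do not say whether the 2 ChIP samples came from separate embryo collections, so the spread between them may be technical. The reference gene table is that of release 6, whereas the regions are placed on release 5. Coordinates of different releases were not mixed, so regions were not assigned to genes, and the planned comparison of gene lists was not run.

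Covered length was the union of the regions of a list, divided by the scaffold length in the header to give a covered share in percent. The 5 major arms are X, 2L, 2R, 3L and 3R. The other scaffolds are the small chromosome 4, the 6 heterochromatin scaffolds whose names end in Het, and U, the sequence not assigned to a chromosome. Unsequenced or repeated bases within scaffolds were counted in their lengths. Overlap of the replicates was measured as the Jaccard index, the shared covered length divided by the length covered in either, and as the percent of regions with at least 1 bp in a region of the other replicate. Chance was estimated from 1000 circular shifts of replicate 2 within each scaffold, with a one-sided permutation p whose smallest possible value is 0.001. Intervals (95%) for differences between X and autosomal arms and for correlations came from 1000 resamplings of 1 Mb blocks. Chance for uncalled stretches came from 1000 random placements of the same widths within each arm, without overlap. The resampling intervals cover variation along the genome, not between embryos. Intervals of shares of regions are exact Clopper-Pearson intervals (95%) and treat regions as independent, which neighbouring regions are not. A two-sided exact sign-flip permutation test over 2 replicates cannot go below p = 0.5, so no test across samples was run, and values are given as mean ± SD (n = 2).

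Named regions followed a rule set before the data were examined: the 10 widest and 10 highest-scoring regions of the combined list, and the 5 widest regions of each replicate without overlap in the other. The comparison of X with autosomal scores, the overlap by width (against 200 circular shifts), the 1 Mb windows and the uncalled stretches were chosen after seeing the data. Alternatives were a 50% reciprocal overlap, only regions at or above the median score of their list, equal numbers of top-scoring regions, uniform random placement, merging of regions less than 1 kb apart, the major arms alone, and leaving out each ChIP replicate. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The interval code was tested on simulated data built on the 12225 regions of replicate 1 on the major arms. In a simulated pair with 59.98% of regions kept in place, 62.1% were recovered as shared at 50% reciprocal overlap. For 100 independent pairs, replicate 1 was set against the widths of replicate 2 placed uniformly at random, and 2 passed p of 0.05. Uniform placements do not cluster, so this does not give the error rate of the shift test where both lists cluster.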

Results

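H3K27me2, a histone mark placed by Polycomb repressive complex 2, was mapped in wild-type Oregon-R fly embryos aged 14 to 16 h, in 2 ChIP samples with 2 inputs. The deposited lists give regions and the authors' scores without read counts, so the depth is unknown. Positions are on FlyBase release 5 and were not matched to genes. Replicate 1 had 12968 enriched regions covering 36.2 Mb, and replicate 2 had 11483 regions covering 28.5 Mb. On the major arms the regions took up 26.0% ± 4.25 of the sequence (SD, n = 2). Median region width was 2118 bp in replicate 1 and 2005 bp in replicate 2, and the widest regions spanned 25459 and 19884 bp. The authors' combined list held 17184 regions covering 58.6 Mb, which is 46.2% of the major arms. Regions of at least 10 kb numbered 131 in replicate 1, 47 in replicate 2 and 741 in the combined list. No region was narrower than 1301 bp in either replicate list or than 1001 bp in the combined list.

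The first comparison asked where along the chromosomes the mark was called. Called H3K27me2 regions were frequent on the euchromatic arms and sparse elsewhere. Unsequenced or repeated bases count in the scaffold lengths, and the mapping settings are not given. Low shares therefore cannot be told apart from sequence that reads could not reach. Arm 2R had the largest covered share, at 30.7% ± 5.07, followed by 3R at 27.3% ± 4.66, 3L at 26.2% ± 4.29, 2L at 24.7% ± 4.18 and X at 21.3% ± 3.00 (SD, n = 2 throughout). Chromosome 4, a small and largely heterochromatic chromosome, had only 3.29% ± 1.26 of its sequence in regions, with 26 regions in replicate 1 and 16 in replicate 2. The 6 heterochromatin scaffolds together had 9.46% ± 2.45, from 1.52% ± 0.442 on YHet to 14.6% ± 2.92 on 3RHet. YHet held only 3 regions in replicate 1 and 2 in replicate 2. Unassigned sequence (U) had 4.17% ± 1.21. In each replicate every major arm lay above chromosome 4, U and every heterochromatin scaffold, and the lowest major arm of replicate 2 (X, 19.2%) also lay above the highest heterochromatin scaffold of replicate 1 (3RHet, 16.7%). The combined list kept this order for chromosome 4 at 8.07% and for the heterochromatin scaffolds at 23.9%.

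**Figure D1:**
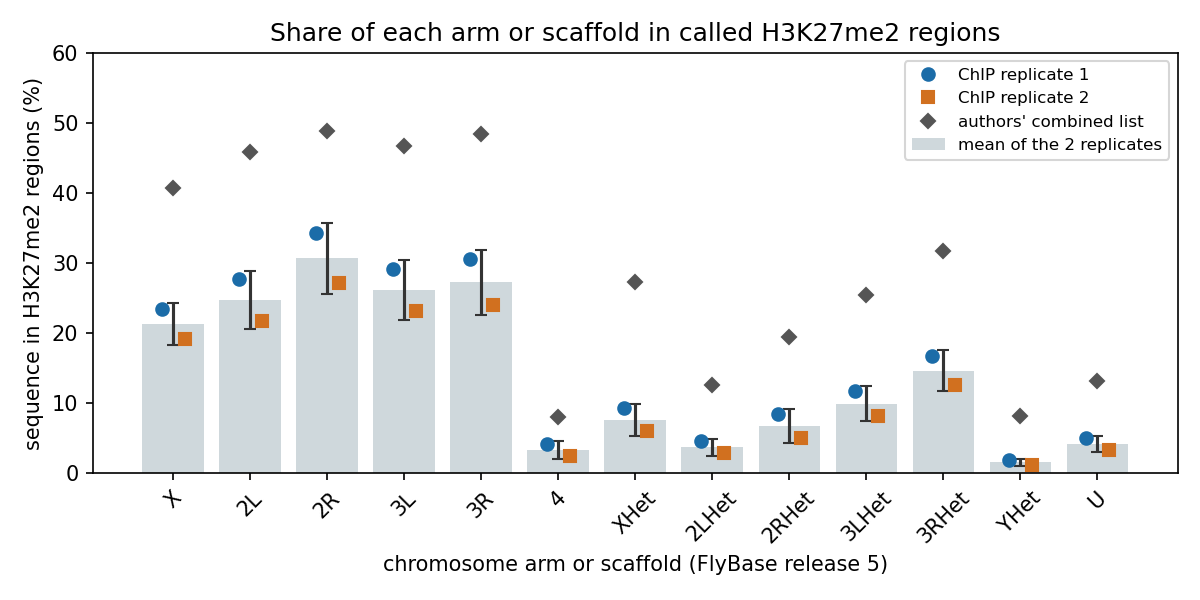
Percent of each arm or scaffold in called H3K27me2 regions. Bars give the mean of the 2 ChIP replicates with the SD as error bar, circles and squares the single replicates and diamonds the authors' combined list. Chromosome 4 lies at 3.29% and the major arms between 21.3% and 30.7%.

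Among the major arms, X had the lowest covered share in replicate 1, in replicate 2 and in the combined list. The sample titles do not name the sex of the embryos, so the copy number of X is not known. Without read counts, a lower share of X cannot be told apart from fewer reads per base on X. In replicate 1, X minus the 4 autosomal arms was -6.90 percentage points (95% interval -9.95 to -3.63), with 23.4% against 30.3%. In replicate 2 the difference was -4.73 points (-7.49 to -2.20), with 19.2% against 23.9%. These intervals cover windows along the arms, not the spread between whole arms. The autosomal arms also differed among themselves, from 27.7% (2L) to 34.3% (2R) in replicate 1 and from 21.8% to 27.1% in replicate 2. One given arm of 5 is lowest by chance in 20% of cases in a single list, and the lists share the same genome and are not independent draws of arms. The difference depended on the score threshold. With regions at or above the median score of their own list, X minus autosomes was 0.10 points in replicate 1 (-2.80 to 3.67) and 1.97 points in replicate 2 (-0.22 to 4.19). With the top 10% of scores in each list, X was above the autosomes, with 6.94% against 4.26% in replicate 1 and 6.18% against 2.75% in replicate 2.

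Regions on X carried higher scores than autosomal regions within each list. The median score was 0.626 on X and 0.554 on the autosomal arms in replicate 1, a difference of 0.072 (95% interval 0.062 to 0.083). In replicate 2 the medians were 0.706 and 0.619, a difference of 0.087 (0.077 to 0.097). With only regions at or above the median score of their list, the difference was 0.031 in replicate 1 and 0.044 in replicate 2. A randomly chosen X region scored above a randomly chosen autosomal region in 66.6% of draws in replicate 1 and 71.1% in replicate 2. X regions were slightly narrower, with a median of 2051 bp against 2161 bp in replicate 1 and 1950.5 bp against 2026 bp in replicate 2. Among the single autosomal arms, 2R had the highest median scores, 0.577 in replicate 1 and 0.635 in replicate 2, both below X.

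**Figure D2:**
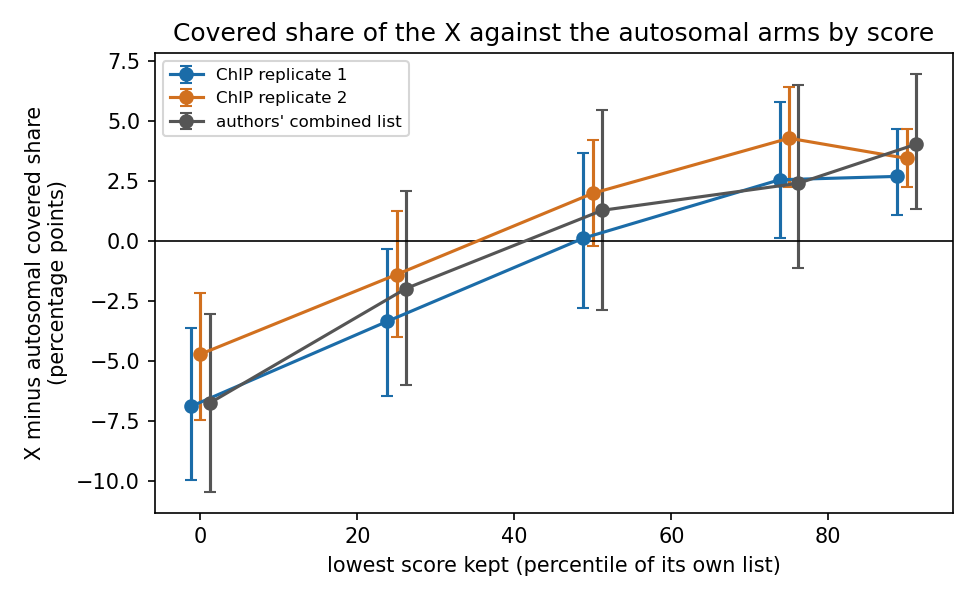
Covered share of X minus that of the 4 autosomal arms, in percentage points, against the lowest score kept, as a percentile of each list. Points are the 2 ChIP replicates and the authors' combined list, with 95% intervals over 1 Mb blocks. The difference runs from -6.90 in replicate 1 with all regions to 2.68 with the top 10% of scores.

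Along the arms, the covered share differed between neighbouring megabases. Over the 117 full windows of 1 Mb, covered shares of the replicates correlated with a Spearman's rho of 0.954 across windows, which are not independent replicates. Replicate 1 was higher in 116 of these 117 windows. The highest window was 3L from 22 to 23 Mb, with 53.0% ± 6.77 covered (SD, n = 2), and the next proximal window, 23 to 24 Mb, had 7.58% ± 1.48. On 2R the most proximal window, 0 to 1 Mb, was the lowest of all at 3.40% ± 1.63, whereas the window from 4 to 5 Mb had 46.0% ± 6.58, the second highest. On 2L the window from 19 to 20 Mb had 37.6% ± 4.04 and the window from 22 to 23 Mb had 10.9% ± 3.49. Proximal ends lie at high coordinates on X, 2L and 3L and at low coordinates on 2R and 3R. The most proximal windows of 3R and X did not fall to such low shares. The lowest windows outside the proximal ends were on X, at 12.7% ± 2.25 from 16 to 17 Mb and 13.0% ± 1.49 from 8 to 9 Mb.

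**Figure D3:**
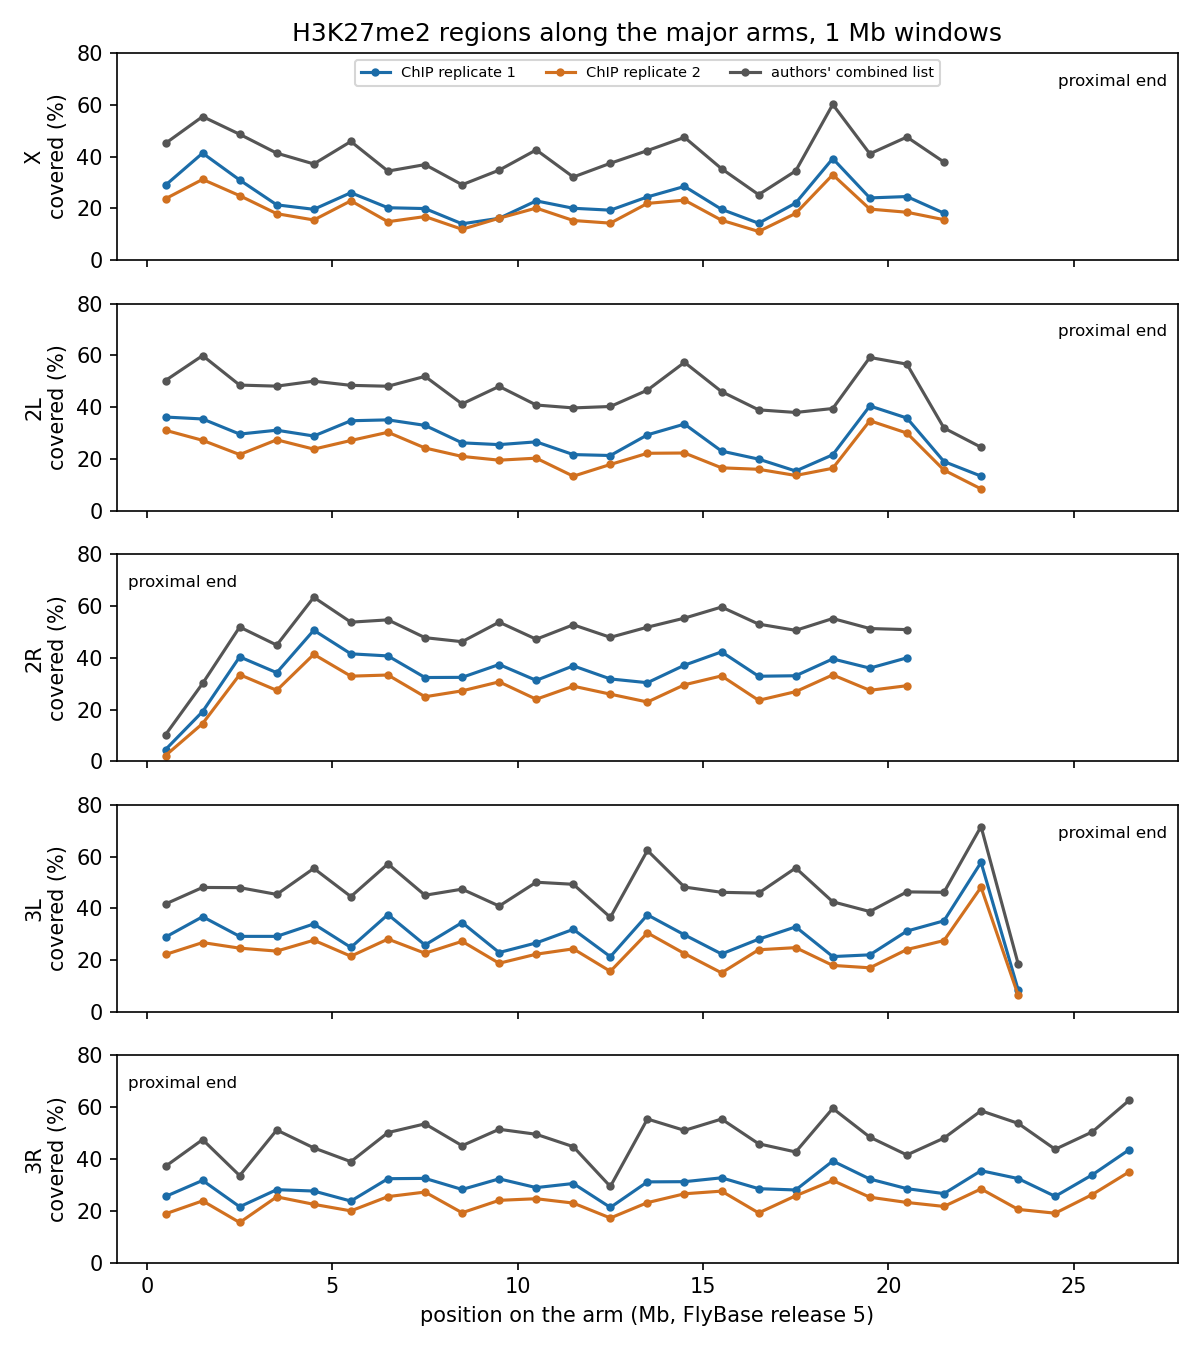
Percent of each full 1 Mb window in called regions along the 5 major arms, for the 2 ChIP replicates and the authors' combined list. The windows next to the proximal ends of 2R, 3L and 2L are among the lowest (3.40%, 7.58% and 10.9% as the mean of the replicates), and the 3L window at 22 to 23 Mb is the highest at 53.0%.

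Of the 10 widest H3K27me2 regions of the combined list, 5 lay on 2R. The widest spanned 56991 bp on 2R from 4685868 to 4742858, with 96.4% of its length in regions of replicate 1 and 82.1% in regions of replicate 2. The second spanned 50979 bp on 3L from 22185070 to 22236048, with 80.6% and 75.7% covered in replicates 1 and 2. Next in width were a region of 45359 bp on 2R from 2392606 to 2437964 and a region of 41327 bp on 2R from 5199098 to 5240424. The widest on X spanned 38911 bp from 1293896 to 1332806, and the widest on 3R spanned 36929 bp from 6276566 to 6313494. Across all 10, between 70.0% and 99.4% of the length was covered in replicate 1 and between 62.6% and 86.7% in replicate 2. Each of the 10 overlapped several regions of each replicate list, between 3 and 8 in replicate 1 and between 6 and 13 in replicate 2.

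The highest-scoring regions of the combined list were of another kind. Scores of the top 10 ran from 3.30 to 3.63, against a median of 0.429 over the list, and all 10 were between 1001 and 1061 bp wide. Of these, 6 lay on U, 1 each on 3RHet and YHet, and 2 on major arms, on 2L from 12894514 to 12895514 and on 3L from 23660828 to 23661840. The highest lay on U from 2984410 to 2985454 with a score of 3.63. All 10 had 0 bp in regions of either replicate, and 7 shared a single score of 3.30. No region of a replicate list was narrower than 1301 bp, so regions of these widths could not appear as such in either. Across the whole combined list, by contrast, score rose with width (Spearman's rho of 0.536 across regions).

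The arms also held long uncalled stretches. In total, 107 stretches of at least 50 kb on the major arms had no region in any of the 3 lists, whereas random placement of the same regions gave 0.137 on average and at most 3 in 1000 placements (one-sided permutation p = 0.001, the smallest it can give). The longest was 188589 bp on 3R from 12615545 to 12804133, with regions in all 3 lists on its far side. In the 200 kb after it, 28.7% was covered in replicate 1 and 28.1% in replicate 2. The 200 kb before it had 14.4% and 13.2% covered, and included a second uncalled stretch of 106503 bp from 12480751 to 12587253. Others of at least 100 kb lay on X from 16160843 to 16294881 (134039 bp), on 2L from 21415229 to 21545851 (130623 bp) and on 2R from 295339 to 425659 (130321 bp), and 13 stretches reached that length, 4 of them on X. On chromosome 4 the longest ran from 26001 to 165256 (139256 bp).

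**Figure D4:**
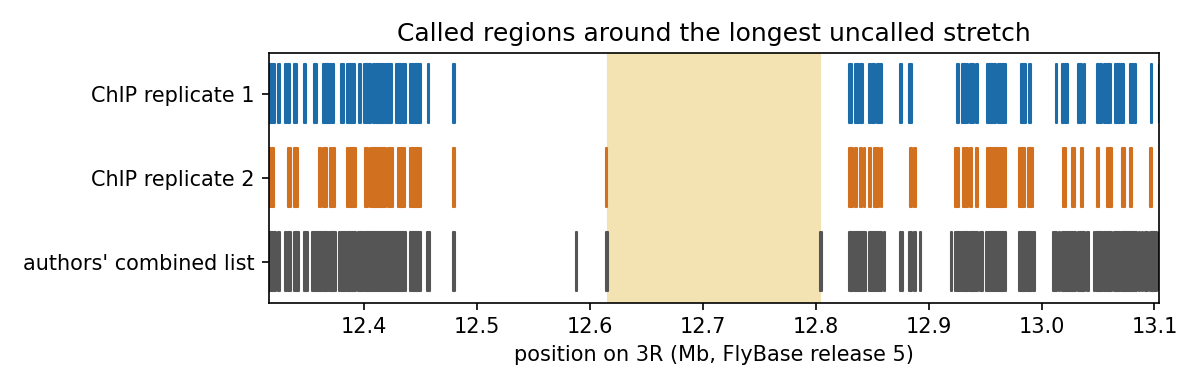
Called regions (bars) of the 2 ChIP replicates and the authors' combined list on 3R, with the longest uncalled stretch, 188589 bp, shaded. The horizontal axis is the position in Mb on FlyBase release 5. A second stretch of 106503 bp without regions lies to its left.

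The second comparison asked how far the ChIP replicates called the same sequence. They shared 21.6 Mb, which was 59.8% of the sequence covered in replicate 1 and 75.9% of that in replicate 2. The Jaccard index was 0.502, against a mean of 0.145 and a maximum of 0.185 in 1000 circular shifts (one-sided permutation p = 0.001, the smallest it can give). In replicate 1, 68.8% of regions overlapped a region of replicate 2, where shifts gave 39.2% on average, and in replicate 2 the share was 82.8%, where shifts gave 45.05%. The chance value of the index depends on the covered share, so arms were not ranked by it. The index was 0.565 on 2R, where circular shifts gave 0.179 on average and at most 0.324. It was 0.473 on X (shifts 0.118, at most 0.281). On chromosome 4, with few regions, it was 0.266 (shifts 0.018, at most 0.264).

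Wide regions were shared far more often than narrow ones. In the narrowest 10% of replicate 1 regions (median 1365 bp) 37.8% overlapped replicate 2 (95% Clopper-Pearson interval 35.1% to 40.5%), and shifts gave 31.3%. In the widest 10% (median 6361 bp) the share was 99.3% (98.7% to 99.7%), where shifts gave 56.8%. The corresponding shares of replicate 2 were 60.9% and 99.6%, where shifts gave 38.4% and 60.4%. The 4052 regions called in replicate 1 alone had a median width of 1711 bp, against 2535 bp for shared ones, and a median score at percentile 32.2 of their list, against 59.3. For the 1980 regions of replicate 2 alone, the median width was 1578.5 bp and the median score percentile 33.3. The widest region of replicate 1 without overlap in replicate 2 spanned 7608 bp on 3L from 12362757 to 12370364, followed by 6561 bp on 3L from 2830241 to 2836801, and the next 3 lay on 2R, 2L and 3L. In replicate 2 the widest such region spanned 4978 bp on 3R from 13661582 to 13666559, followed by 4498 bp on X from 18936221 to 18940718, and the next 3 lay on X, 3R and 2R.

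**Figure D5:**
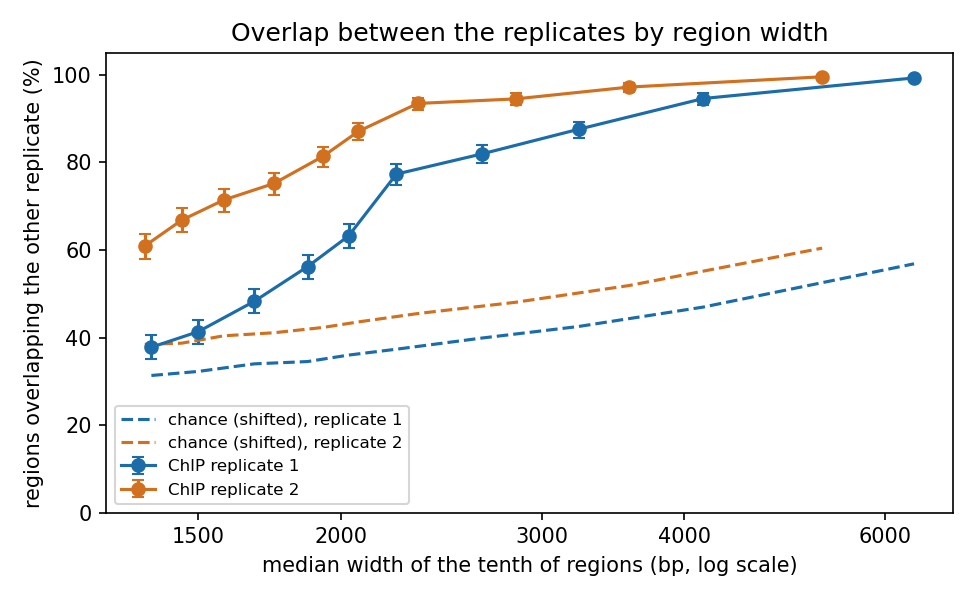
Percent of regions that overlap the other ChIP replicate by at least 1 bp, in classes of 10% of the regions by width (median width in bp, log scale), with 95% Clopper-Pearson intervals. Dashed lines give the mean of 200 circular shifts. Shares rise from 37.8% to 99.3% in replicate 1 and from 60.9% to 99.6% in replicate 2.

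The ranks of the scores were moderately shared. Over 10522 overlapping pairs of regions, Spearman's rho between replicate scores was 0.453 (95% interval 0.433 to 0.472), a correlation across regions, which are not independent replicates. The pairs are all overlapping combinations of 8916 shared regions of replicate 1 and 9503 of replicate 2, so some regions entered more than once. Restricting the pairs to those overlapping by 50% of each region left 6339 pairs and gave 0.603. That rule keeps only pairs of similar width, and score rose with width within each list (rho of 0.659 in replicate 1 and 0.587 in replicate 2).

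The last comparison set the authors' combined list against the replicate lists. Of its 17184 regions, 7068 (41.1%, 95% Clopper-Pearson interval 40.4% to 41.9%) overlapped both replicates, 3214 replicate 1 only, 1559 replicate 2 only and 5343 (31.1%) neither. Nearly all replicate sequence was contained in it, with 99.3% of replicate 1 and 98.8% of replicate 2. Sequence covered in neither replicate made up 16.1 Mb, or 27.5% of the combined list. Regions overlapping neither replicate had a median width of 1381 bp, against 4381 bp for those overlapping both, and a median score at percentile 28.7 of the list, against 74.2. The combined list held regions from 1001 bp and the replicate lists only from 1301 bp. Some of the regions overlapping neither were therefore too narrow to appear as such in a replicate list. Regions called in 1 replicate alone were also present in it, 99.4% of those of replicate 1 and 97.0% of those of replicate 2. The combined list was therefore not the intersection of the replicate lists, and its covered shares are not means of theirs.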

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

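The Jaccard index and the shares of overlapping regions stayed above chance in every alternative run for them. The Jaccard index lay between 0.420 (regions at or above the median score) and 0.516 (regions less than 1 kb apart merged). The 50% reciprocal rule and uniform random placement could not change the index itself. Uniform placement altered only the chance values. At 50% reciprocal overlap, 48.9% of replicate 1 and 55.2% of replicate 2 regions counted as shared. The lower covered share of X, -5.82 percentage points as the mean of both replicates, kept its sign with equal numbers of top-scoring regions (-5.01), with merging (-6.06) and with either replicate left out (-6.90 to -4.73). It reversed to 1.04 points with regions at or above the median score. With thresholds chosen after seeing the data it was -2.39 at percentile 25 and reversed to 3.40 at percentile 75 and 3.05 at percentile 90. Low-scoring regions, removed by construction, made up more of the autosomal than of the X coverage. With the median-score threshold in replicate 1, the covered share fell from 23.4% to 18.9% on X and from 30.3% to 18.8% on the autosomes. The rho of scores of shared pairs rose to 0.603 with 50% reciprocal overlap and was 0.336 with width in place of the score; the cause was not tested. The share of combined regions overlapping both replicates fell to 29.4% when at least 50% of the region had to be covered, and to 38.8% with regions at or above the median score of each list; the cause of the second change was not tested. Also chosen after seeing the data, the share of draws in which an X region scored above an autosomal region of its list (68.9% as the mean of the replicates) was 60.7% with regions at or above the median score and 64.0% in the combined list, and the uncalled stretches of at least 50 kb numbered 196 in replicate 1, 268 in replicate 2 and 109 in the combined list taken alone. No paired analysis was possible because the inputs have no region list here and the labels cross the numbers of ChIP and input. Leaving out a replicate gives no value for the overlap or the score correlation, which need both. The covered share of genes in the fixed lists was not run, since the gene table is of another release. Without read counts, depth limits every statement on uncalled sequence.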

Other observations

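All tests of explanations in this part were chosen after the results were seen.

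The highest scores of the combined list sat in narrow regions (median 1039 bp in the top 1%, 2325 bp in the rest), and 133 of these 172 top regions lay on heterochromatin scaffolds or U, which held 9.40% of the whole list. On the same scaffolds lay 42.3% of the top 1% in replicate 1 and 49.6% in replicate 2, against 5.53% and 4.71% of all regions, but there the top regions were not narrow in the same way (2707.5 bp against 2117 bp in the rest of replicate 1, 1896 bp against 2005 bp in replicate 2). The replicate lists held no region narrower than 1301 bp, which limits this comparison of widths. A candidate explanation is that such scores are log2 ratios of small read counts: 77.3% of the top 1% of the combined list lay within 1e-06 of a log2 ratio of whole numbers up to 30, counted from its most common score (0.303), against at most 3.49% with 200 random offsets and 7.56% on a log10 scale. The regions on such ratios and those on heterochromatin scaffolds or U are equal in number but not the same set, with 104 in both. For the replicate lists this cannot be told apart from other origins, since 16.2% (replicate 1) and 34.8% (replicate 2) lay on such ratios and larger counts would give ratios outside this set; no biological explanation was tested.

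X had fewer called bases but higher scores. The copy number of X in these embryos is not known, and fewer reads per base on X were not tested as an origin of either. A stricter threshold on X that only removed low-scoring regions would leave X with no more high-scoring regions per Mb than the autosomes. Among the top 10% of scores on the major arms, the X density was 2.04 times the autosomal one in replicate 1 (95% interval 1.58 to 2.63). In replicate 2 it was 2.74 times (2.28 to 3.27). These values argue against that form of threshold only. Whether a stricter threshold also changed the extent or score of regions was not tested, as the caller is not known. Larger counting noise on X cannot be told apart from other origins: the excess in the widest 20% was 1.41 (1.22 to 1.82) and 1.11 times (0.888 to 1.39) that in the narrowest 20%, but how noise falls with width was not measured, and width follows score in these lists. A different X share in the ChIP and its input for another reason cannot be told apart from a difference in the mark, because that needs read counts. The share of draws in which an X region scored higher differed by 4.56 percentage points between the replicates, whose inputs were separate per the labels. A higher H3K27me2 level in the marked part of X may be a biological explanation and was not tested.

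The 107 stretches of at least 50 kb without a region in any list may hold sequence without the mark or sequence that reads could not reach. They may also hold the mark at a level below the caller's threshold, which is not known. The tables argue against uniform random spacing of the regions, which gave at most 3 such stretches in 1000 placements. Covered shares already varied between 1 Mb windows, so this outcome shows only that regions cluster along the arms. The lists are not separate evidence, as the combined list alone gave 109 such stretches. The positions also argue against repeats at the proximal arm ends as the source of most of the longest stretches. Of those of at least 100 kb, 84.6% (11 of 13, 95% Clopper-Pearson interval 54.6% to 98.1%) lay over 2 Mb from the proximal end. Their density was 2 per 10 Mb within 2 Mb of the proximal end, from only 2 stretches, and 1.01 per 10 Mb beyond it. The share of arm length beyond 2 Mb, 91.6%, lies within that interval, so 13 stretches are too few to tell these densities apart. Whether proximal repeats gave some of the stretches stays open. Repeats or assembly gaps within the arms were not tested, and no biological explanation was tested.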
